A study of Mus musculus with 6 samples.

How the data were processed

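Total RNA of MC38 and MC38r cells was measured on Illumina MouseWG-6 v2.0 bead arrays, with 3 arrays per line and 6 arrays in all. Per the labels, cells were grown in RPMI with foetal calf serum, RNA was purified on RNeasy columns, and biotin-labelled cRNA was made with the Ambion MessageAmp kit. All 6 arrays lay on 1 chip, with the 3 MC38 arrays on its first sections and the 3 MC38r arrays on its last, so that position on the chip and line cannot be told apart. The labels number the arrays as replicates without saying whether these were separate cultures, so every p-value measures the spread between samples that may be technical repeats.

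Per the file headers, the authors exported the probe table from GenomeStudio 1.9.0 with quantile normalization, and its deposited values are intensity on a linear scale for 45281 probes. Between 35.0% and 35.1% of the probes of each array lie under 0 and the columns share their quantiles, so the background had already been subtracted. The deposited detection values are a score between 0 and 1, which is 1 minus the detection p-value. Control probe signals in the deposited sample table are intensity before background subtraction. The deposited gene table that is called non-normalized holds, as far as its values show, the same normalized gene signals plus a shift of 31.29 to 33.71 per array, and the deposited series values are those signals quantile-normalized once more. The authors also deposited a comparison of the lines for 6244 genes, with a linear ratio or fold change of MC38r over MC38, its log2 value, and an unadjusted and an adjusted p-value. That table stops at an unadjusted p of 0.05, and the test behind it is not stated.

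The design, written before the data were examined, assumed raw signals. Since the probe table is the least processed one that carries detection values, it was used. Its signals went through the normexp background correction of limma 3.58.1 (nec, with detection p-values and an offset of 16), log2 transformation and quantile normalization in R 4.3.3. Probes with a detection p under 0.01 on at least 3 of the 6 arrays were kept, which left 13990 probes. Array names were matched to current symbols through a table of mouse gene names, in which 22775 of 30854 names were found (16223 by symbol, 5684 by an older symbol and 868 by gene number), and the others kept their array name. A further 28 names had been turned into dates or numbers by a spreadsheet before deposition. The brightest kept probe stood for each gene, which gave 9799 genes. The same table, which uses the GRCm38.p6 assembly, served to tell which genes neighbour each other. The arrays name no genome build, so no positions are given.

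The 2 lines were compared gene by gene with limma (lmFit and eBayes, group as the only term), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All values are normalized log2 signals, and each fold change is MC38r over MC38. Where the probe of a gene was not above background on any array of 1 line, the fold is given as "at least", computed against the lowest signal called above background on each array (5.19 to 5.36 on the log2 scale). The order of genes at that limit carries no information. For arrays the number of samples limits the precision: the median standard error of a log2 fold change was 0.15.

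Before the data were examined, 31 gene lists were fixed, and 27 of them had the 5 measured genes needed for a test. Each was tested with camera against all other genes, with a preset correlation of 0.01 and beside it a correlation estimated from the data, and with fry, which compares a list with no other genes. Counts are given over all genes tested and, where they differ, adjusted over the list alone. Named genes follow a rule fixed at the same time. They are the 10 largest rises and the 10 largest falls among changed genes whose arrays do not overlap between the lines, with predicted transcripts counted but not named. To these were added 8 prostanoid genes of interest (Ptgs1, Ptgs2, Ptges, Hpgd and Ptger1 to Ptger4), and from each list up to 3 members past the threshold and 2 that were not, by size of change. Any other gene is said to have been chosen after its values were seen. Some genes that the rule names are not reported here.

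Alternatives covered the background correction, the normalization (median scaling, cyclic loess, and the deposited series values), the offset (50), the probe filter (none, or stricter), the mean of all probes of a gene, a replicate block, the variance model, array weights, an unmoderated test, the correlation between genes and the omission of each array. Others were chosen after seeing the data: the shifted gene signals, the omission of both arrays that deviate together, and each omission with the same probes kept. When arrays were left out, the filter was applied again to those that remained, and with 2 arrays of a line left it dropped genes above background in that line alone. That loss alone can move the counts and lists, so each omission was also run with the probes and genes of all 6 arrays. A chip block was not run, as there was 1 chip. The procedure was tested on simulated data, drawn with the measured mean and spread of each gene and no difference between the lines, in which sets of 50 genes were then shifted: 10 were recovered at a log2 change of 0.5, 39 at 1, 49 at 2 and 50 at 4, with 4 false calls among 152. Few genes were shifted there and the noise was independent, whereas 56.5% of genes passed in the data and some arrays deviate together. The simulated recoveries and false calls are therefore not rates for the real comparison. The control signals entered no test, and the gene-level signal columns of GenomeStudio were not used here except to check the shifted table. Preparation and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.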

Results

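Basal gene expression was measured in 2 mouse colorectal cancer lines, MC38 and MC38r. MC38 is sensitive to eicosapentaenoic acid (EPA), an omega-3 fatty acid. MC38r is resistant, with a 6-fold higher IC50 after continuous exposure to EPA. Each line was represented by 3 arrays. Between 28.35% and 30.14% of the 45281 probes were above background on the MC38 arrays and between 28.97% and 30.52% on the MC38r arrays, with a median of 44 beads behind each probe. Control signals were lower on the MC38r than on the MC38 arrays, without overlap, for housekeeping genes (10450 ± 205, SD, n = 3, against 12183 ± 654), biotin (5703 ± 405 against 6684 ± 528), Cy3 hybridization (3104 ± 93.5 against 3379 ± 158) and low stringency (2376 ± 69.1 against 2585 ± 119), and stood at 79.3 in both lines for labelling. Below, values are mean normalized log2 signals ± SD over the 3 arrays of a line.

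The comparison asks which transcripts differ between resistant and sensitive cells that, per the labels, were grown alike. With 1 line of each kind, differences tied to resistance cannot be told apart from other differences between the lines. MC38r cells had far higher levels of interferon-responsive transcripts and a high level of the hormone transcript Prl, which was at background in MC38. The matrix transcripts Lox, Mmp2 and Col6a3 were abundant in MC38 and at background in MC38r, smooth muscle actin, Acta2, was 85.3-fold lower, and 19 of 21 measured genes of cholesterol synthesis and uptake were lower. In all, 5536 of 9799 genes passed the limma test (56.5%), of which 2820 rose and 2716 fell in MC38r. A change of at least 2-fold was fitted for 2342 of them, 1150 upward and 1192 downward, and 2107 reached it when genes at background were held at their bound. With the series values that the authors normalized once more, the count of 2-fold changes was 1501. The 2 lines did not overlap for 6122 genes (62.5%, where chance gives 10%). A total of 833 genes were above background on every array of 1 line and on none of the other, 408 of them in MC38r and 425 in MC38.

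**Figure D1:**
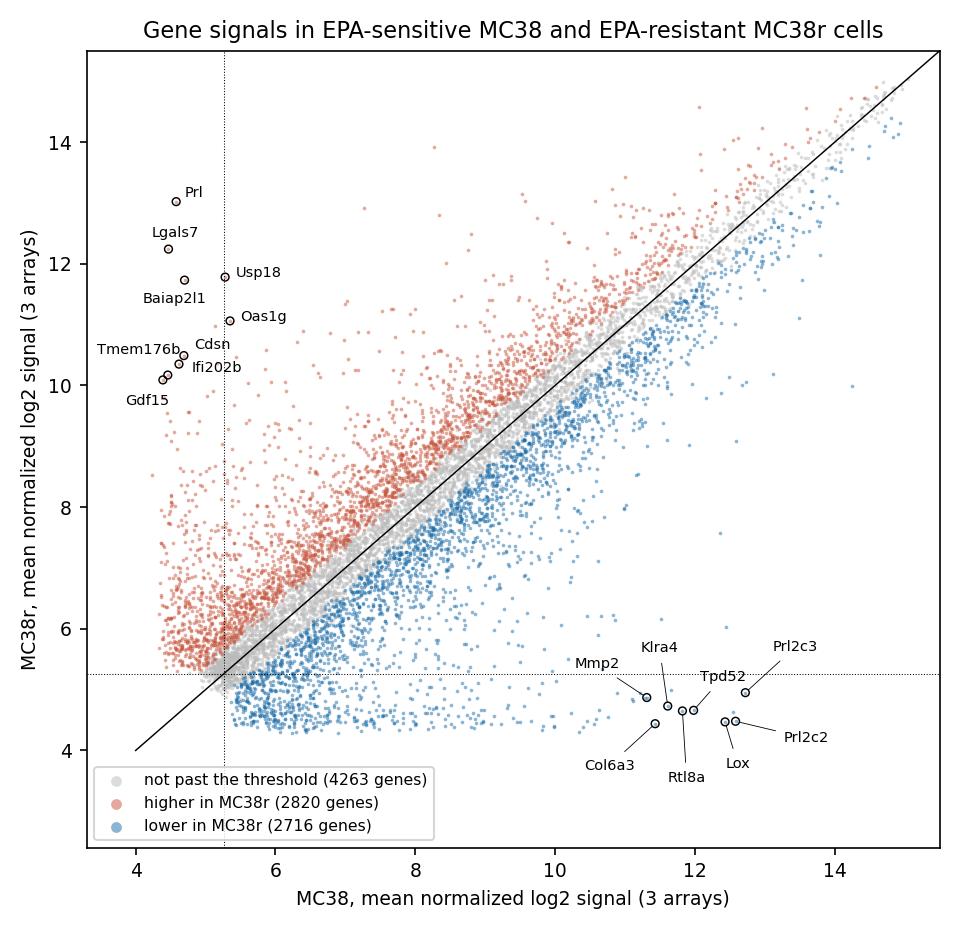
Mean normalized log2 signal of each of 9799 genes in MC38 (x axis) and MC38r (y axis), 3 arrays per line, with genes past the threshold coloured by direction, the named largest changes circled, and dotted lines at the mean of the lowest signals called above background. The 2820 genes that rose and the 2716 that fell lie on either side of the diagonal, and 7 of the 10 largest rises and 9 of the 10 largest falls have 1 line at background by the probe used, with a dimmer Lgals7 probe above background on 2 MC38 arrays.

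The largest rises were led by Prl, which encodes the pituitary hormone prolactin. Its signal was 4.58 ± 0.11 in MC38, where it was not above background, and 13.02 ± 0.06 in MC38r, a rise of at least 213-fold (adjusted p = 7.1e-10). Lgals7, which encodes the keratinocyte lectin galectin-7, was at least 124-fold higher by its brightest probe (12.24 ± 0.04 in MC38r), although a dimmer probe was above background on 2 MC38 arrays. Baiap2l1, a regulator of actin at membranes, rose by at least 87-fold, Cdsn (corneodesmosin, a skin adhesion protein) by at least 36.8-fold, Ifi202b (an interferon-inducible DNA-binding protein) by at least 33.5-fold, Tmem176b by at least 29.6-fold and Gdf15, a stress-induced cytokine, by at least 28-fold. The interferon-induced genes Usp18 and Oas1g rose from just above background on 2 MC38 arrays, by 90.7-fold and 52.5-fold as fitted. The remaining 1 of the 10 largest rises was a predicted transcript.

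Among the largest falls, all 8 named genes had a mean signal of 11.31 or more in MC38 and were not above background on any MC38r array. Lox, which encodes the collagen cross-linking enzyme lysyl oxidase, went from 12.43 ± 0.03 to 4.47 ± 0.11, a fall of at least 146-fold (adjusted p = 7.1e-10). Col6a3, a collagen VI chain, was lower by at least 73.1-fold and Mmp2, a gelatinase, by at least 67.1-fold. Tpd52 (at least 107-fold) and the retrotransposon-derived gene Rtl8a (at least 95.4-fold) were lower too. Prl2c2 (proliferin, at least 162-fold), Prl2c3 (at least 178-fold) and the lectin-like receptor gene Klra4 (at least 82.6-fold) belong to families of near-identical copies, and a probe can read several copies of such a family. The other 2 falls were predicted transcripts.

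Prostanoid genes, which encode the enzymes and receptors that turn EPA and arachidonic acid into signals, moved in few cases. Ptgs1, the constitutive cyclooxygenase, rose 5.43-fold in MC38r, from 5.23 ± 0.1, above background on 2 of 3 arrays, to 7.67 ± 0.03 (adjusted p = 3.4e-07). A further probe of Ptgs1 rose by 2.11 on the log2 scale, and another was above background on 1 array. Abcc4, an exporter of prostaglandins, rose 2.42-fold (7.22 ± 0.3 to 8.49 ± 0.09, adjusted p = 0.00018), and the prostaglandin F synthase Akr1b3 was 1.66-fold lower (7.52 ± 0.16 to 6.79 ± 0.28, adjusted p = 0.0051). The inducible prostaglandin E synthase Ptges stood at 8.08 ± 0.16 in MC38 and 7.85 ± 0.19 in MC38r (adjusted p = 0.21), and Ptges2 and Ptges3 did not pass the test either. Ptges3 passed without MC38 replicate 3 (-0.57 on the log2 scale, against -0.38 with it), and Ptges2 without MC38 replicate 1 when the probes of all 6 arrays were kept (-0.48, adjusted p = 0.048). Transcripts of the inducible cyclooxygenase Ptgs2, the prostaglandin-degrading enzyme Hpgd and the prostaglandin E2 receptors Ptger2, Ptger3 and Ptger4 were not above background on any array, and Ptger1 was not matched to a probe. Of the 8 measured members of the list 2 rose, 1 fell and 5 did not pass, and no shift of the list as a whole was detected (adjusted p = 0.87). In the list of lipoxygenase and epoxygenase enzymes, with 4 measured genes too short for a test, the epoxide hydrolase Ephx1 rose 10.5-fold (7.04 ± 0.35 to 10.44 ± 0.17) and Cyp4f13 rose 1.66-fold, while Alox5ap was 1.64-fold lower and Cyp4f16 did not pass. Cyp4f13 did not pass without MC38r replicate 2 (0.68 on the log2 scale, adjusted p = 0.058) or without MC38r replicate 3 (0.64, adjusted p = 0.066).

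**Figure D2:**
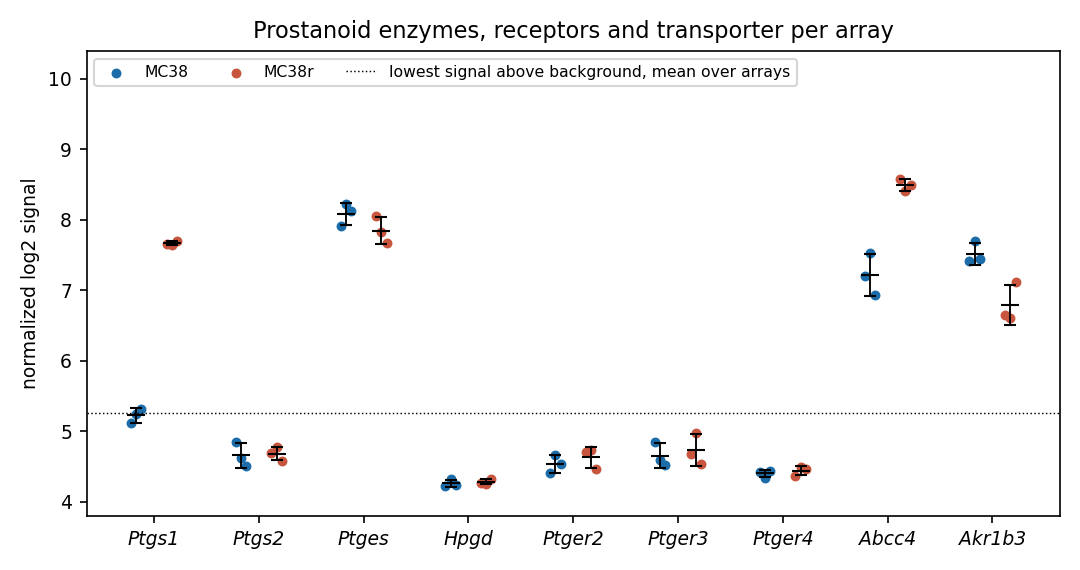
Normalized log2 signal (y axis) of prostanoid genes on each array of MC38 and MC38r (points, 3 per line), with mean and SD bars and a dotted line at the mean of the lowest signals called above background. Ptgs1 stands at 5.23 in MC38 and 7.67 in MC38r, Abcc4 is higher and Akr1b3 lower in MC38r, and Ptgs2, Hpgd and Ptger2 to Ptger4 lie under the line.

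Enzymes of cholesterol synthesis were lower in MC38r almost throughout. Of 21 measured genes 19 fell and none rose, with a median log2 change of -1.55 (adjusted p = 3.7e-08, and 0.042 with an estimated correlation). The methylsterol oxidase Msmo1 fell from 10.65 ± 0.41 to 6.21 ± 0.23, a 21.6-fold difference. Acat2, the thiolase that starts the pathway, was 7.91-fold lower. The regulators Insig2 (-0.1 on the log2 scale) and Scap (-0.43) did not pass, although Scap did without MC38 replicate 2 (-0.83). Genes of fatty acid synthesis, desaturation and elongation went the same way: 16 of 21 fell and 1 rose, with a median of -0.69 (adjusted p = 0.00035, but adjusted p = 0.064 with an estimated correlation). The elongases Elovl4 (at least 6.01-fold) and Elovl6 (9.94 ± 0.35 to 7.24 ± 0.11, 6.52-fold) and the desaturase Scd2 (8.81 ± 0.01 to 6.28 ± 0.35, 5.79-fold) fell most.

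Other lipid lists held changes in both directions, with no shift detected as a whole. In fatty acid oxidation 8 of 26 genes fell and 4 rose (adjusted p = 0.29). Acaa1a was 2.2-fold and Acadm 2.1-fold lower, and Ech1 was 2.24-fold higher. In fatty acid uptake and activation 4 of 13 rose and 4 fell (adjusted p = 0.87), with Vldlr, a lipoprotein receptor, 3.74-fold higher and Mfsd2a, a carrier of omega-3 lysophospholipids, 3.61-fold lower. Of 11 measured PPAR-responsive genes 6 rose and 4 fell (adjusted p = 0.5), and the acyl-CoA thioesterases Acot1 and Acot2 rose 10.8-fold and 5.48-fold as fitted, with Acot2 above background on 1 MC38 array. In triglyceride storage 6 of 17 rose and 8 fell (adjusted p = 0.55), with Agpat5 at least 2.84-fold lower and Dgat2, above background on 1 MC38 array, 2.26-fold higher as fitted. In phospholipid remodelling 3 of 17 rose and 8 fell (adjusted p = 0.27), and Lpcat3, which loads polyunsaturated chains into phospholipids, was 2.55-fold lower.

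Interferon-responsive genes rose together in MC38r. Of 34 measured genes 29 rose, 1 fell and 4 did not pass, with 30 rising when adjusted over the list alone. The median log2 change was 3.08, or 2.86 with genes at background held at their bound (adjusted p = 1.6e-13, and 0.042 with an estimated correlation). Usp18, which removes the ubiquitin-like ISG15, went from 5.28 ± 0.27 to 11.78 ± 0.07, the antiviral synthetase Oas1g from 5.35 ± 0.06 to 11.06 ± 0.14, and Oas2 rose by at least 15.3-fold. Trim25 (0.38 on the log2 scale) and Irf1 (-0.26) did not pass, although Trim25 did without MC38 replicate 3 (0.5) or MC38r replicate 1 (0.48). In the list of antigen processing and MHC class I 14 of 25 rose and 3 fell, with a median of 0.75 (adjusted p = 0.0087, but adjusted p = 0.091 with an estimated correlation). Its largest rises were H2-K1 (5.02 ± 0.22, above background on 1 MC38 array, to 9.82 ± 0.19), H2-Q6 (19.3-fold) and H2-Q8 (8.66-fold), from a family of closely related genes. The reading of H2-K1 depends on the probe, since another probe of it went from 6.47 ± 0.25 to 5.26 ± 0.2 and became the one used, at -1.25 on the log2 scale, when MC38 replicate 2 and MC38r replicate 1 were both left out and the filter dropped the first. Probes of H2-D1, chosen after its values were seen, differed as well: 1 went from 4.5 ± 0.08 to 11.34 ± 0.21, beside others that rose by 1.53 and 1.36 on the log2 scale.

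Stress-responsive genes rose as well. Of 23 measured p53-responsive genes 20 rose and 2 fell, with a median of 1 on the log2 scale (adjusted p = 3.7e-05, but adjusted p = 0.063 with an estimated correlation). Gadd45a, a DNA damage-inducible gene, rose 12.9-fold (8.8 ± 0.14 to 12.49 ± 0.07), the cell cycle inhibitor Cdkn1a rose 11.1-fold (8.76 ± 0.23 to 12.22 ± 0.15), and Trp53inp1 rose by at least 9.58-fold. In the unfolded protein and amino acid stress response 20 of 36 genes rose (21 when adjusted over the list alone) and 7 fell, with a median of 0.68 (adjusted p = 0.02, but adjusted p = 0.091 with an estimated correlation). Ppp1r15a, a phosphatase subunit that restores translation after stress, rose 9.52-fold, the pseudokinase Trib3 rose 5.35-fold and the transcription factor Atf3, above background on 1 of 3 MC38 arrays, rose 4.35-fold as fitted. Without MC38 replicate 3 the adjusted p of this list was 0.063, but 0.027 when the same probes were kept.

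**Figure D3:**
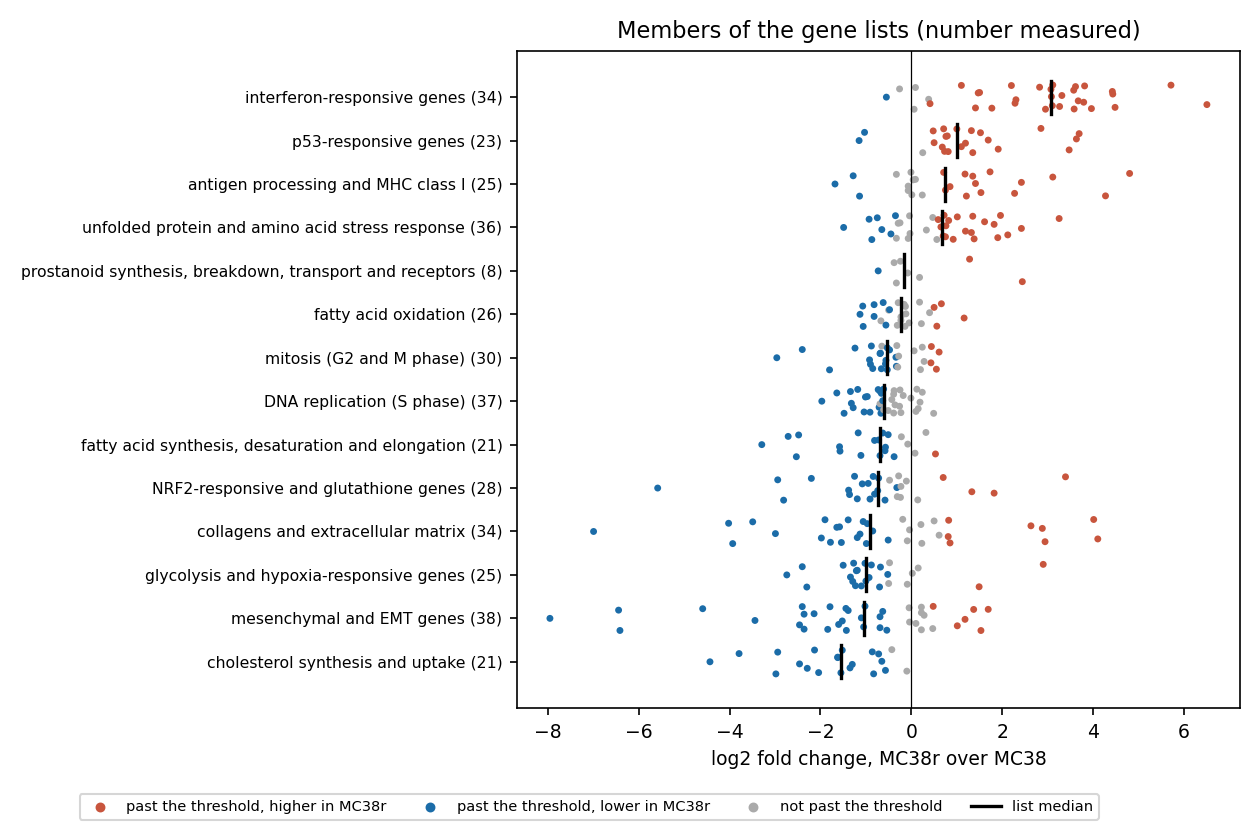
Log2 fold change of MC38r over MC38 (x axis) for each measured member (points, coloured by direction where past the threshold) of the 11 lists that shifted and of 3 further lists, with list medians as black bars and the number measured in brackets. Medians run from -1.55 for cholesterol synthesis to 3.08 for interferon-responsive genes.

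Mesenchymal genes were lower in MC38r: 24 of 38 fell and 6 rose, with a median of -1.04 (adjusted p = 0.00035, but adjusted p = 0.064 with an estimated correlation). Beside Lox and Mmp2, smooth muscle actin, Acta2, fell from 12.44 ± 0.13 to 6.03 ± 0.28, an 85.3-fold difference. Fibronectin, Fn1, did not pass (0.47 on the log2 scale), although it did without MC38 replicate 2 (0.7). Among collagens and matrix genes 19 of 34 fell and 8 rose, 9 when adjusted over the list alone. Col6a3 and the fibrillin gene Fbn1 (at least 12.5-fold) were lower, while the fibulin gene Fbln2 rose 17.1-fold, from 5.75 ± 0.18 to 9.85 ± 0.14. The matrix list had a median of -0.91, or -0.57 with genes at background held at their bound, and missed the threshold (adjusted p = 0.058). With 1 array left out and the same probes kept it had an adjusted p of 0.047 to 0.065, and passed without MC38 replicate 3 alone.

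Glycolysis and hypoxia-responsive genes fell in 18 of 25 cases, 19 when adjusted over the list alone, and 2 rose. The median was -1, or -0.75 with genes at background held at their bound (adjusted p = 0.00035, but adjusted p = 0.087 with an estimated correlation). The phosphofructokinase Pfkm was 6.69-fold lower (10.52 ± 0.09 to 7.77 ± 0.09) and the prolyl hydroxylase Egln3, above background on 1 MC38r array, 5.29-fold lower as fitted, whereas the enolase Eno2 rose by at least 5.05-fold. Among NRF2-responsive and glutathione genes 17 of 28 fell and 4 rose, with a median of -0.73, or -0.65 with bounds (adjusted p = 0.0028, but adjusted p = 0.087 with an estimated correlation). The carbonyl reductase Cbr3 was lower by at least 26.7-fold and the quinone reductase Nqo1 was 7.65-fold lower (8.69 ± 0.06 to 5.75 ± 0.05), while Ephx1 rose. Hmox1 (-0.48 on the log2 scale) and Keap1 (-0.31) did not pass, although Hmox1 did without MC38r replicate 3 (-0.71) and Keap1 without MC38 replicate 2 (-0.43).

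Cell cycle genes were moderately lower. In S phase 18 of 37 fell and none rose, with a median of -0.61 (adjusted p = 0.00038, but adjusted p = 0.091 with an estimated correlation). The chromatin assembly factor Chaf1b (3.91-fold), the ribonucleotide reductase Rrm2 (3.13-fold) and the helicase subunit Mcm4 (2.8-fold) fell most. In mitosis 18 of 30 fell and 4 rose, with a median of -0.53 (adjusted p = 0.0087, but adjusted p = 0.091 with an estimated correlation). Dlgap5, a spindle protein, was lower by at least 5.54-fold, the checkpoint kinase Bub1b was 5.26-fold lower and the kinesin Kif23 3.48-fold lower. With an unmoderated test the lists of S phase (adjusted p = 0.23), mitosis (0.25), unfolded proteins (0.27) and glycolysis (0.058) did not pass. In that setting the list test took the t-statistics of the genes instead of their signals, so the loss cannot be put down to moderation alone.

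For the remaining lists no shift was detected. Of 26 cytokine and NF-kappaB genes 11 rose and 8 fell (adjusted p = 0.64), with Il11 at least 19.4-fold and Ccl5 8.63-fold higher and Ccl7 at least 6.53-fold lower. Of 19 Wnt genes 5 rose and 8 fell (adjusted p = 0.48), and Wnt7b (at least 40.5-fold), Dkk3 (at least 8.9-fold) and Sox9 (7.46-fold) fell. Among 11 efflux transporters 5 rose and 3 fell (adjusted p = 0.69), with the multidrug transporter Abcb1b 4.06-fold higher. Of 26 apoptosis regulators 12 rose and 8 fell (adjusted p = 0.69), with Casp9 at least 3.75-fold and Casp6 4-fold lower and Casp1 3.35-fold higher. Of 29 peroxide defence genes 5 rose and 11 fell (adjusted p = 0.6), with the transferrin receptor Tfrc 8.05-fold lower. Oxidative phosphorylation (13 of 57 rose, 13 fell) and cytosolic ribosomal proteins (10 of 54 rose and 7 fell, 8 and 6 when adjusted over the list alone) each had an adjusted p of 0.87. Of 9 measured epithelial genes 4 rose and 3 fell (adjusted p = 0.86). The median and the mean of a list differed in sign for prostanoid, Wnt, oxidative phosphorylation and ribosomal genes.

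Markers of other cell types were mostly at background in both lines. Of 33 macrophage, myeloid and lymphocyte markers on the array 3 were above background on all MC38r arrays and 3 on all MC38 arrays. Measured lists were short. Among 2 myeloid markers Cd14 rose 1.34-fold and Cd68, above background on 1 MC38r array, was 1.56-fold lower as fitted. Among 2 lymphocyte markers Lck rose by at least 1.24-fold and Cd8b1 was 1.9-fold lower. The Cd8b1 value rests on 1 probe (10.63 to 9.7), while its other probes stood at 5.04 and 4.57 in MC38 and at 5.18 and 4.6 in MC38r. Among 3 endothelial markers Flt1 rose 3.89-fold while Eng and Egfl7 fell. Cd14 was near the threshold without MC38 replicate 1 (adjusted p = 0.05, and 0.047 with the same probes kept) or MC38r replicate 2 (0.051 and 0.049). Of 7 fibroblast markers 3 rose and 3 fell (adjusted p = 0.95), with Col3a1 at least 2.37-fold lower and Pdgfra 2.13-fold higher.

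Over all 27 lists tested, 11 shifted with the preset correlation, 4 upward and 7 downward, and 2 of them, cholesterol synthesis and interferon-responsive genes, held with an estimated correlation. By fry, 23 of the 27 moved one way on balance and 27 changed in either direction. Since fry compares a list with no other genes and 56.5% of all genes changed, these counts say little about the lists themselves. Probes of the same gene went past the threshold in opposite directions for 66 of 1755 changed genes with several probes.

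Arrays of 1 line resembled each other far more than those of the other line. Pearson correlations across genes, which are not independent replicates, were 0.982 to 0.995 within MC38, 0.988 to 0.995 within MC38r and 0.855 to 0.866 between the lines, and the first principal component, which parted the lines, held 89.6% of the variance. MC38 replicate 2 and MC38r replicate 1 deviated from the other arrays of their line in the same genes (correlation across genes of their deviations 0.64). Without both, and with the same probes kept, 6174 genes changed and 2361 of them at least 2-fold. The lines also lay on different sections of the chip, so that section and line cannot be told apart.

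In the comparison deposited by the authors, 6244 genes had an unadjusted p of at most 0.05 and 1354 an adjusted p under 0.05. Of the 5021 genes also tested here, 4965 had the same sign and 4592 (91.5%) passed the threshold with that sign. Log2 fold changes had a correlation of 0.977 across genes. Since both used the same arrays, neither is independent evidence for the other.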

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

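Direction and call held for most results under the 28 alternatives, of which the shifted gene signals, the omission of both deviating arrays and 7 omissions with the same probes kept were chosen after seeing the data. Without an array the filter drops genes seen in the line that has 2 arrays left, so those values mix the loss of genes with that of the array, and same probes are the fairer test. Changed genes ranged from 4390 (without MC38r replicate 3, 4832 with the same probes) to 6521 (array weights), and 4896 passed with the replicate block, although deviations of arrays with the same number correlated at -0.49, -0.47 and 0.34 across genes, so the numbers do not pair the arrays. Of 105 named genes past the threshold, 99 passed with the same sign in every setting that measured them. Genes changed at least 2-fold numbered 1501 both with the series value table and with shifted gene signals, which test 7898 genes, average probes and carry added signal. On all 9799 genes, added signal alone (offset 50) gave 1612 and the mean of probes alone 2286. Lists past the threshold numbered 7 with the unmoderated test, where S phase had an adjusted p of 0.23, mitosis 0.25, unfolded proteins 0.27 and glycolysis 0.058. That setting also ran the list test on t-statistics instead of signals. With an estimated correlation 2 lists passed. Fatty acid synthesis and mesenchymal genes had 0.064, NRF2 and glycolysis 0.087, p53 0.063, and S phase, mitosis, unfolded proteins and MHC class I 0.091. The estimate lay under the preset 0.01 for p53 (-0.04), mesenchymal (-0.02), NRF2, mitosis and unfolded protein genes (-0.01 each), fatty acid synthesis and MHC class I (0 each). A higher correlation between genes thus does not account for their larger p-values. For S phase (0.03) and glycolysis (0.02) it lay above. In simulated data with independent noise, a shifted list had a camera adjusted p of 1.1e-43 (preset correlation) and 0.0027 (estimated). The estimated setting thus gave a far larger p-value there without correlated genes. A miss in that setting does not show that the genes of a list are correlated. Other causes were not tested. The unfolded protein list had 0.06 without both deviating arrays and 0.0074 to 0.063 with 1 array left out, but 0.017 and 0.013 to 0.027 with the same probes. Collagens and matrix passed with the series value table (0.025), shifted signals (0.025), no filter (0.028) and the mean of probes (0.037), and had 0.047 (without MC38 replicate 3) to 0.065 with 1 array left out and 0.079 without both, with the same probes. The filtered values, 0.042 to 0.78 and 0.8, follow from which genes the filter drops and decide nothing. Log2 changes reversed for Atf4 with the series value table (-0.39), the mean of probes (-1.62) and shifted signals (-0.38), all of which average probes. Pdia6 reversed without MC38r replicate 1 (-0.6), without MC38r replicate 2 (-0.57) and without both deviating arrays (-0.62), with a range of -0.6 to 0.88 when 1 array was left out, and H2-K1 reversed without both deviating arrays (-1.25), where a second probe of it was used. With the same probes neither reversed: Pdia6 had 0.4 to 0.88 with 1 array left out and 0.74 without both, and H2-K1 4.81 without both. Signal over background limits the folds: by the probe used, 855 changed genes were not above background on any array of 1 line.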

Other observations

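Of the tests in this part, those of sequence variants on any probe, separate origin (recounted on other probes), immune cells, chromosome segments, probes shared by related neighbours and other splits of the arrays were chosen after the result was seen, and all genes named in this part, apart from Mcm6 and H2-K1, were chosen after their values were seen. Hoxc9 (9.22 ± 0.16, SD, n = 3), Hoxc10 (9.81 ± 0.23), Hoxd10 (7.64 ± 0.21), En1 (9.65 ± 0.08) and Gata6 (8 ± 0.09) were above background on every MC38 array and on no MC38r array, and Hoxb7 was above background on MC38r arrays alone (9.79 ± 0.24). Both lines lacked signals of the epithelial genes Krt18, Epcam and Cdh1 above background, and Krt8 was above it on 1 array of each line. Vimentin, Vim, was abundant in MC38 (13.53 ± 0.13) and lower in MC38r (11.74 ± 0.02). The desaturase Fads2, which acts in the synthesis of EPA from shorter omega-3 fatty acids, was lower in MC38r by 2.48 on the log2 scale.

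The tumour suppressor genes Cdkn2a (11.1 ± 0.1 to 4.84 ± 0.21, with 3 probes at background in MC38r) and Cdkn2b (10.75 ± 0.18 to 4.55 ± 0.1) were abundant in MC38 and at background in MC38r. Mtap, the direct neighbour of Cdkn2a, stood at 12.01 ± 0.08 and 12.44 ± 0.08. Xist, the RNA that silences an X chromosome, was above background in MC38 (7.3 ± 0.21) and not in MC38r (4.42 ± 0.06). Trp53 rose by 0.68 on the log2 scale and its target Mdm2 by 1.52.

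A first pattern is the set of 100 genes switched by at least 8-fold between the lines by their brightest probe, 30 of them higher in MC38r and 70 higher in MC38. Of 38 other probes of 32 of these genes 35 (92.1%) moved at least 2-fold the same way, which decides nothing, since a gene with a probe bright in both lines is mostly represented by that probe and left out; among 51 genes with several probes and any of them switched, 55 of 68 other probes (80.9%) did so, which argues against sequence variants under single probes as the main source for those genes, while 9 of them and the 68 genes with 1 kept probe stay open. A steady trend along the chip is excluded as the source of these switches. Within a line the change from first to last section was -0.4% of that between the lines (quartiles -3.4% and 1.5%), where such a trend would give about 67%. Smaller changes were not tested for it, and biotin signals fell from 7268 on MC38 replicate 1 to 5450 on MC38r replicate 3. A step between the lines' sections that acts on all probes alike is removed by the quantile normalization, so the switches in both directions (30 and 70) decide nothing about it. Housekeeping signals were lower on the MC38r arrays, without overlap (10450 ± 205 in MC38r, 12183 ± 654 in MC38). A step that acts on single genes stays open. That the lines do not share a recent origin may explain the pattern, and was tested by counting genes with a switched probe beside a probe bright in both lines, as different alleles would give, against a bar of 5: a first count on the brightest probe of each gene gave 0, which that choice of probe keeps low, and a recount on any probe, made after that 0 was seen, gave 5 (Fgfr1op2, Glrx, Mak16, Mcm6 and Rmdn3), without Msn, where 1 probe went from 10.67 to 5.34, just above background on 2 MC38r arrays, and another from 7.77 to 7.56, and without Zfp330, where 1 probe fell by 5.85 and another went from 9.26 to 10.27, a change of 1.01 that just exceeds 2-fold. Other transcript forms give such genes too, so separate origin and change during EPA exposure cannot be told apart here, and different alleles under the probes of H2-K1 and H2-D1 stay open too.

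A second pattern is the rise of interferon-responsive genes. Markers of immune cells argue against such cells in the MC38r cultures as the source: 3 of 33 (9.1%) were above background on all MC38r arrays, while Ptprc, Lyz2 and Cd3e, abundant in such cells, were at background on every array. A steady trend along the chip would give about 67% of the difference between the lines within each line, and the value was -2.3% (quartiles -7.3% and 0.4%). The median log2 change was 3.08 for these genes and 0.03 for all genes tested, and housekeeping signals were lower in MC38r (10450 ± 205 against 12183 ± 654). Quantile normalization removes a step between the chip sections that acts on all probes alike. The median of 0.03 for all genes was thus set in advance and decides nothing about such a step. What stays open is a step confined to some probes, an infection or other trigger in the MC38r cultures, and a lasting state of the resistant line, none of which was tested.

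Neighbouring genes changed together, the last of the patterns weighed. Log2 fold changes of 8593 genes placed on chromosomes correlated at 0.176 between direct neighbours and at 0.102 between genes 20 places apart (Spearman, across genes, which are not independent), against at most 0.032 and 0.035 in 1000 shuffles of the gene order. The value at 20 places argues against probes shared by related neighbours, which lie side by side, and is consistent with gain or loss of chromosome segments in one of the lines; shared regulation of large domains may give it as well and was not tested. By shuffles of single genes, the median change of 14 of 20 chromosomes departed from that of all genes, and of 275 X-linked genes 123 fell and 44 rose (median log2 change -0.33, adjusted permutation p = 0.0002, from the smallest p that 10000 shuffles can give). Such shuffles treat genes as independent, although neighbours changed together. The permutation p-values are therefore too small, and the count of 14 chromosomes is likely too high.

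Groups of 3 and 3 arrays allow 10 splits, too few for a share under 0.05. All splits but the real one hold arrays of both lines in both groups, so the difference between the lines counts as spread there. The counts of 0 in those splits follow largely from that mixing and decide nothing. The real split alone, 1 of 10, gave 5536 changed genes by limma, against 0 in each of the other splits, which gave at most 320 at an unadjusted p under 0.05. It was also the 1 split with 2342 genes changed at least 2-fold, against a highest other of 0. For lists past the threshold with the preset correlation, 1 split of 10 reached the real count of 11, but the highest other split gave 10, so that this count by itself hardly parts the real split from the others; with an estimated correlation the real split gave 2 lists and every other split 0.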
